A study of Homo sapiens with 6 samples.

How the data were processed

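RNA was sequenced from PA-1 cells, a human line from an ovarian teratocarcinoma, in 6 libraries, 1 for each of the labels Vector, Wnt3a, RIPK1, RIPK2, RIPK3 and RIPK4. Per the labels' protocols, total RNA was isolated on silica columns and made into sequencing libraries by the usual Illumina procedure. The 5 plasmid groups took 8 µg of plasmid for 48 h, and the Wnt3a group took 200 ng of ligand for 16 h. Groups were taken from the transfection field of the sample labels, and table columns were matched to samples by title.

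The deposited table gives the authors' RPKM (reads per kilobase of gene, scaled to the library's total), with 1 column for each library and no pooling, per the file headers. It lists 20494 genes by symbol and numeric identifier, each value to 5 significant digits. The submitters' processing notes name GSNAP, DESeq and hg19. Their versions and roles, the gene annotation, the counting rule and the reads behind the per-million factor are not given in the sources used here. No scaling between libraries is recorded, so RPKM was used as deposited.

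Read numbers were recovered from the RPKM values. Where whole reads are divided by a length and a library total, the values of a gene across libraries stand in whole-number ratios after 1 factor for each library. Lengths from 15 to 30000 bases were tried for each gene. A length was accepted where all 6 values came out as whole reads within the rounding of the printed digits. This solved 16446 genes (80.2% of the table), 11082 of the 11881 genes analysed (93.3%) and 95.3% of the 17263 genes detected in at least 2 libraries. Solved lengths were in a median ratio of 0.998 to the lengths in GENCODE 29. The totals behind the per-million factor came to 17.2 M reads for Vector, 18.5 for Wnt3a, 19.5 for RIPK1, 19.3 for RIPK2, 19.1 for RIPK3 and 18.3 for RIPK4. For genes without a solution, reads were approximated from the GENCODE length. Since the annotation's build is GRCh38, it served only for transcript length, GC content and overlap of genes, and no coordinates were taken from it. Gene classes came from RefSeq by gene identifier, which matched 20382 genes and left 112 unmatched.

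Genes with a mean RPKM of at least 1 over the 6 libraries were kept. They comprised 11381 protein-coding genes, 173 small RNAs and 137 pseudogenes, and 26 had no RefSeq match. Fold changes against Vector were differences of log2(RPKM + 1). With 1 library per group there is no spread between replicates, so no p-value was computed. A gene was counted as higher or lower at a difference of at least 2-fold on that scale. The kinase transfected in a library was left out of its counts. For named genes the ratio of RPKM values is given with an exact binomial 95% interval from the reads of both libraries. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and such a ratio compares libraries, not conditions. Against a count of 0, a ratio was taken over a floor of 3 reads in that library, beside the lower limit of its two-sided interval.

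Before the data were examined, 24 gene lists were fixed. They cover Wnt/beta-catenin targets, primitive streak and mesendoderm, pluripotency, neural and ectodermal progenitors, NF-kB targets, interferon-stimulated genes, immediate early and AP-1 or ERK targets, p53 targets, unfolded protein and integrated stress responses, heat shock, and cell death and necroptosis. The others are epidermal differentiation, TGF-beta and BMP targets, Notch and Hedgehog targets, S phase and mitosis, cholesterol and fatty acid synthesis, hypoxia and glycolysis, ribosomal proteins, replication-dependent histones and housekeeping genes. Markers of 4 other kinds of cell were included: haematopoietic, fibroblast and mesenchymal, endothelial, and trophoblast with extraembryonic endoderm. For each list the median log2 fold change of its kept members was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called higher above the 97.5th percentile and lower below the 2.5th percentile, where it kept at least 3 members. This was possible for 23 lists in each of 5 comparisons. The percentile describes these libraries and is no test of the condition.

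Genes to be named were chosen by a rule fixed in advance. It takes the transfected kinases, then in each comparison the 10 largest rises and 10 largest falls among genes at least 2-fold apart. Unnamed transcripts and small nuclear, nucleolar, micro and ribosomal RNAs were counted but not named. To these it adds up to 4 members of each list with the largest difference in any comparison, and AXIN2, LEF1, SP5, NKD1, T and DKK1 whatever their values. Genes below a mean RPKM of 1 are named only as list members with their RPKM. The rule took 152 genes, not all of which are reported here. A few genes outside it are marked where they appear.

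Similarity to Wnt3a was the correlation across genes of the fold changes of a kinase library and of the Wnt3a library. Both fold changes share the Vector library. Unchanged libraries were therefore simulated with counting error alone to give the correlation, covariance and overlap of gene counts that arise with no effect. Overlaps of independent lists were the product of both counts divided by the number of genes. The correlation was also recomputed with no library shared: Vector stayed the reference of 1 side and another kinase library became that of the other, which gives 6 choices. The same was done for RIPK2 with RIPK3 after the data were seen, with Wnt3a, RIPK1 or RIPK4 as the other reference.

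After the data were seen, fold changes were found to follow transcript GC content, which was known for 11779 of the kept genes (99.1%). A lowess curve of the fold changes on GC with a span of 0.2 was subtracted from each comparison as an added alternative. Genes without a GC value drop out of it, which accounts for part of any fall in gene counts. Correlations with GC were computed over genes with at least 50 mean reads. A minimum of 20 mean reads was also added then. Alternatives fixed in advance were a pseudocount of 0.1, a minimum mean RPKM of 5, no minimum, rescaling by median ratios, the median of the other transfected libraries as reference, and disjoint references.

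Read recovery, gene counts, list calls and GC removal were tested on simulated data. Among 50 genes at each size in a simulation of RIPK4 against Vector, 100% of 4-fold, 84% of 2.5-fold, 80% of 0.4-fold and 92% of 0.25-fold differences were counted, with 14 of 11708 unchanged genes. In a simulation of RIPK1 against Vector without effect, 12 of 11908 genes were counted and 3.5% of random lists were called. Read recovery solved 81.5% of 20318 simulated genes, with every read number right for 98.9% of those solved. In a simulated GC trend for RIPK3 against Vector, Spearman's rho with GC fell from 0.940 to -0.0418 after removal. The counts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.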

Results

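PA-1 cells, a human ovarian teratocarcinoma line with many traits of pluripotent embryonal cells, were profiled by RNA sequencing after overexpression of a receptor-interacting protein kinase or after exposure to Wnt3a. The 6 libraries held 1 sample each of cells given empty vector, RIPK1, RIPK2, RIPK3 or RIPK4 plasmid (8 µg, 48 h) and of cells given Wnt3a (200 ng, 16 h). All 6 library labels stand under a field named transfection, that of the Wnt3a library too. They do not say whether the Wnt3a cells also took a plasmid. Each condition was set against the Vector library, and the kinases were set beside Wnt3a, the ligand that starts canonical beta-catenin signalling, a pathway in which RIPK4 has been placed. Library totals lay between 17.2 M reads for Vector and 19.5 M for RIPK1. Of 20494 genes, 11881 had a mean RPKM of at least 1. A floor of 3 reads, the one-sided 95% limit of a count of 0, came to 0.0769 to 0.0870 RPKM for a transcript of 2 kb. No group has a replicate, so no difference below has a replicate check, no SD or p-value is given, and all values describe these libraries. Log2 fold changes and counts of genes use log2(RPKM + 1), which understates differences of genes with low values. Ratios are of RPKM itself, and the ranges in brackets beside them are 95% intervals that cover counting error only.

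The transfected kinases were examined ahead of all other genes. RIPK4 (gene identifier 54101) stood at 17.9 RPKM in its own library and at 0 in the others, at least 414-fold over the floor of 3 reads in the Vector library (two-sided 95% limit 337). RIPK3 (11035), a necroptosis kinase, stood at 61.4 RPKM with 3167 reads in its own library and at 0 to 0.0384 elsewhere, at least 954-fold over that floor (two-sided limit 775). RIPK2 (8767), which relays signals from NOD receptors, was 2.31-fold higher in its library than in Vector (95% interval 2.09 to 2.56), at 27.4 against 11.8 RPKM. RIPK1 (8737) was 1.30-fold higher (1.20 to 1.41), at 16.6 RPKM with 1416 reads against 12.8 RPKM with 963 reads. The other libraries held 9.35 to 13.4 RPKM of RIPK1 and 8.50 to 11.8 RPKM of RIPK2. All 4 kinases were thus highest in the library that bears their name, with RIPK1 above the next library by the smallest ratio.

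**Figure D1:**
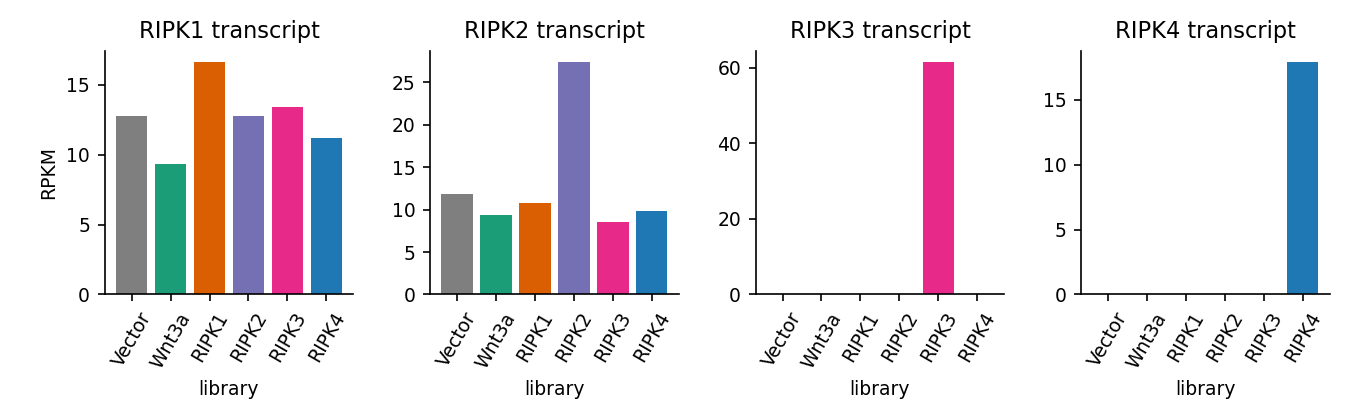
RPKM of RIPK1, RIPK2, RIPK3 and RIPK4 in each of the 6 libraries, on an axis that starts at 0, with 1 bar per library. RIPK3 reached 61.4 and RIPK4 17.9 RPKM in their own libraries and were near 0 elsewhere, whereas RIPK1 reached 16.6 RPKM against 12.8 in Vector.

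Exposure to Wnt3a was accompanied by higher transcripts of known Wnt/beta-catenin targets. CDX1, a caudal homeobox gene, went from 1 read in Vector (0.0327 RPKM) to 618 reads (18.8 RPKM), a ratio of 576 with a counting interval of 103 to 22769. The homeobox genes MSX1 (8.43-fold, 7.27 to 9.82) and CDX2 (13.3-fold, 8.70 to 21.2) were also higher, as was MIXL1, a primitive streak factor, at 3.71 against 0.332 RPKM. Feedback inhibitors of the pathway stood higher too: NKD1 was 5.32-fold higher (4.57 to 6.23), NOTUM 5.25-fold (4.12 to 6.75), DACT1 4.13-fold (3.88 to 4.40), RNF43 3.77-fold (3.34 to 4.25) and AXIN2 2.39-fold (2.24 to 2.56). LEF1, a DNA-binding partner of beta-catenin, was 2.66-fold higher (2.24 to 3.16).

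In the fixed list of Wnt/beta-catenin targets, 28 of 38 genes were kept, 14 of them at least 2-fold higher and none 2-fold lower with Wnt3a. The list median of 0.91 on the log2 scale lay above all 10000 matched random lists. DKK1 and T were at 0 in both libraries, and SP5 stood at 0.0298 RPKM in Vector (1 read) and 0.194 with Wnt3a (7 reads), a ratio whose counting interval of 0.838 to 294 includes 1. Among primitive streak and mesendoderm genes, 3 of 12 kept members were at least 2-fold higher (CDX1, CDX2 and MIXL1) and 1 at least 2-fold lower, and the list median of 0.08 was not called. HIST1H2BE and HIST1H4E completed the 10 largest rises with 28 and 25 reads against 1 and 2. Both belong to a multigene family with near-identical copies and are uncertain.

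Interferon-stimulated genes, which include the antiviral sensors and effectors, were called lower with Wnt3a, with a median of -0.76 and 14 of 33 kept members at least 2-fold lower. No plasmid amount is recorded for the Wnt3a cells, which had 16 h of ligand, against 48 h with 8 µg of plasmid for Vector. Ligand, plasmid and time thus cannot be told apart in any difference between these libraries. IFIT1 stood at 31.2 against 152 RPKM (4.88-fold lower, 4.68 to 5.09), XAF1 at 1.33 against 9.14, and the RNA sensor DDX58 at 6.54 against 25.3. Pluripotency genes were called lower with a median of -0.52 over 14 kept members. SOX2 was 3.09-fold lower (2.95 to 3.25), at 48.1 against 149 RPKM, and PRDM14 2.26-fold lower (2.09 to 2.43). POU5F1, added after its values were seen, stood at 13.2 against 13 RPKM. Outside the lists, the largest falls were SHISA3, an inhibitor of Wnt and FGF receptor maturation (1.73 against 31.6 RPKM), and the retinoic acid hydroxylase CYP26A1 (0.218 against 7.74 RPKM, 35.5-fold lower with an interval of 19.1 to 74.8). The tubulin cofactor TBCA (13.4 against 55.5 RPKM) and POLR3G, a subunit of RNA polymerase III (14.1 against 50.2 RPKM), followed, with PP2D1, MZT1 and HES3. Hypoxia and glycolysis genes (median 0.39, then 0.19 with the GC trend removed) and cholesterol and fatty acid synthesis genes (0.26, then 0.19) were called higher, with ALDOC at 16.0 against 6.68 RPKM. Epidermal differentiation genes were called higher as well at 0.41, a call that ended with the GC trend removed (0.21).

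In all, 80 genes were at least 2-fold higher and 170 at least 2-fold lower with Wnt3a. Small RNAs made up 15 and 31 of these, and 17 and 23 genes had fewer than 20 reads on average. Fold changes followed transcript GC content with a Spearman rho of 0.721 across 11406 genes, and with that trend removed the counts were 41 and 84. The 10 largest rises and 10 largest falls all stayed at least 2-fold apart after the removal, and the calls of the Wnt, interferon and pluripotency lists held at medians of 0.62, -0.72 and -0.22.

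**Figure D2:**
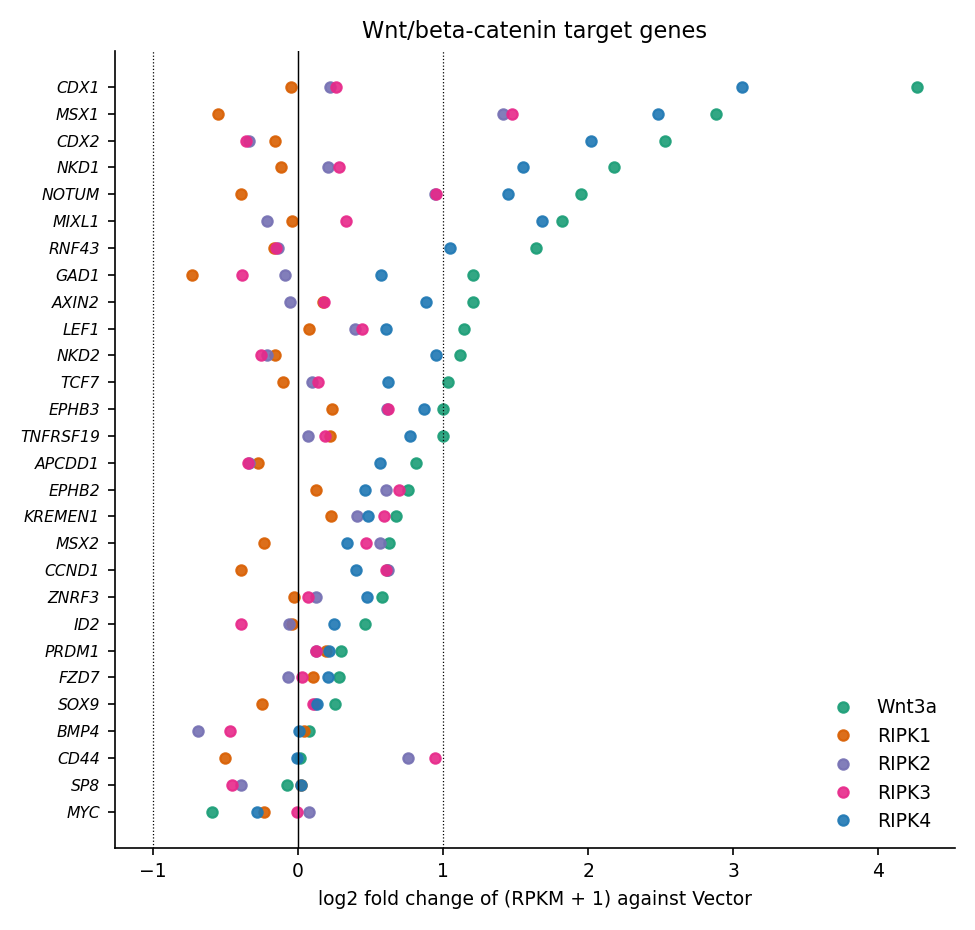
Log2 fold change against Vector, on log2(RPKM + 1), of the kept members of the Wnt/beta-catenin target list (vertical axis, by symbol), with 1 point for each of the 5 other libraries and dotted lines at 2-fold lower and higher. With Wnt3a 14 of 28 members reach the right line and with RIPK4 7 do, whereas with RIPK1 none does.

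RIPK4 was accompanied by higher levels of the same Wnt target list. Its 28 kept members had a median of 0.57, above all 10000 random lists, and 7 were at least 2-fold higher. CDX1 was at 7.61 RPKM with 247 reads against 1 in Vector, MSX1 6.37-fold higher (5.48 to 7.44), CDX2 8.84-fold (5.74 to 14.2), NKD1 3.38-fold (2.88 to 3.98) and NOTUM 3.56-fold (2.77 to 4.63). DACT1, which is not in the list, was 2.97-fold higher (2.78 to 3.17). MIXL1 stood at 3.28 RPKM with 42 reads against 4. AXIN2 was 1.90-fold higher (1.77 to 2.03) and LEF1 1.72-fold (1.43 to 2.07). Beyond the list, NKX1-2, a homeobox gene (6.98 against 2.15 RPKM), and TRIM71, an RNA-binding ubiquitin ligase of stem cells (77.5 against 31.4 RPKM), were among the 10 largest rises. RPL19P12, a retrocopy of a ribosomal protein gene, was too, and is uncertain because reads can be shared with its parent.

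Set directly against Wnt3a, 26 of the 28 kept Wnt targets were lower with RIPK4 and 2 higher, with a median difference of -0.22 and 1 member at least 2-fold lower. RIPK4 and Wnt3a differed by at least 2-fold at 52 genes, 35 higher and 17 lower with RIPK4. Of the 33 interferon-stimulated genes kept, 12 were among those higher with RIPK4 than with Wnt3a. Time, and perhaps plasmid, differed between these groups too, so such differences cannot be put down to the kinase or the ligand. Against Vector the interferon list was not called with RIPK4, at a median of -0.08. Pluripotency genes, called lower with Wnt3a (-0.52), RIPK2 and RIPK3, were not called with RIPK4 (-0.14, and -0.05 with the GC trend removed). SHISA3 was lower here too (2.38-fold, 2.13 to 2.65), at 13.3 RPKM.

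Counted over all genes, 47 were at least 2-fold higher and 46 at least 2-fold lower with RIPK4, of which 30 and 6 were protein coding and 14 and 40 were small RNAs. Rescaling by median ratios moved this split to 35 and 59. Apart from SHISA3, the named falls were SSB, SRP9, CCDC58, TAF1D and NDUFA5, each 2.07-fold to 2.18-fold lower in RPKM. With the GC trend (Spearman rho 0.700) removed, SHISA3 was the 1 named fall of 6 that remained at least 2-fold lower, whereas 9 of the 10 named rises remained. RPL19P12, the other rise, had no GC value. The Wnt list stayed called with a median of 0.42. S phase and mitosis genes were called lower with RIPK4 (-0.13) and fibroblast and mesenchymal markers higher (0.28), and both calls ended with the trend removed (-0.04 and 0.12). Calls made only with the trend removed were higher for stress response (0.23) and cholesterol synthesis genes (0.22), and lower for neural progenitor (-0.20), TGF-beta and BMP target (-0.12), heat shock (-0.12) and histone genes (-0.10).

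The library labelled RIPK1 stood out by low interferon-stimulated transcripts. The list median was -1.54, below all 10000 random lists, and 25 of 33 kept members were at least 2-fold lower than in Vector. IFI27 stood at 7.54 against 200 RPKM (26.5-fold lower, 22.1 to 32.1) and IFI6 at 112 against 896 (8.03-fold lower, 7.65 to 8.43). The oligoadenylate synthetases OAS1, OAS2 and OAS3 were 7.51-fold, 11.3-fold and 7.17-fold lower. IFIT1 was 5.23-fold lower (5.02 to 5.46), the RNA sensor IFIH1 9.31-fold (7.24 to 12.1), XAF1 13-fold (10.2 to 16.7) and IFITM1 4.15-fold (3.91 to 4.40). In this comparison 9 of the 10 largest falls were members of the list, and the other was LGALS3BP (4.26-fold lower, 3.94 to 4.60). B2M, the light chain of MHC class I, was 2.33-fold lower (2.24 to 2.43).

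Low interferon-stimulated genes set RIPK1 apart from the other libraries and not from Vector alone. It held 17 protein-coding genes at least 2-fold below each of the other 5 libraries, of which 11 were in the interferon list. Vector and Wnt3a each held 2 such genes, and RIPK2, RIPK3 and RIPK4 held 0. Of the 33 kept members, 27 were lowest in RIPK1 and 5 in Wnt3a, and all 33 were highest in RIPK2 or RIPK3. Immediate early and AP-1 or ERK targets (-0.35), replication-dependent histones (-0.36), TGF-beta and BMP targets (-0.19), epidermal differentiation (-0.19), p53 targets (-0.12) and cell death genes (-0.10) were also called lower with RIPK1, and all 6 calls held with the small GC trend of this library removed. The Wnt target list was not called at -0.08, with no member 2-fold apart, but was called lower with a pseudocount of 0.1 (-0.14).

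Rises with RIPK1 were few. Of 35 genes at least 2-fold higher, 11 were protein coding, 13 small RNAs and 9 pseudogenes. The 10 largest named rises comprised NACA2, HNRNPCL1, PTTG3P, H3F3C, ATP5EP2, UQCRBP1 and GLUD2, which are retrocopies or close copies of other expressed genes and are uncertain. EDARADD (7.68 against 2.09 RPKM) holds a processed ENO1 copy in its locus on the same strand, which leaves it uncertain too. The others were the noncoding transcript PAR5 (18.9 against 7.53 RPKM) and the homeobox gene BSX (25 reads against 2). There were 65 genes at least 2-fold lower. RIPK1 had little GC trend against Vector (Spearman rho -0.0943), and with it removed the counts over genes with a GC value were 27 and 60.

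**Figure D3:**
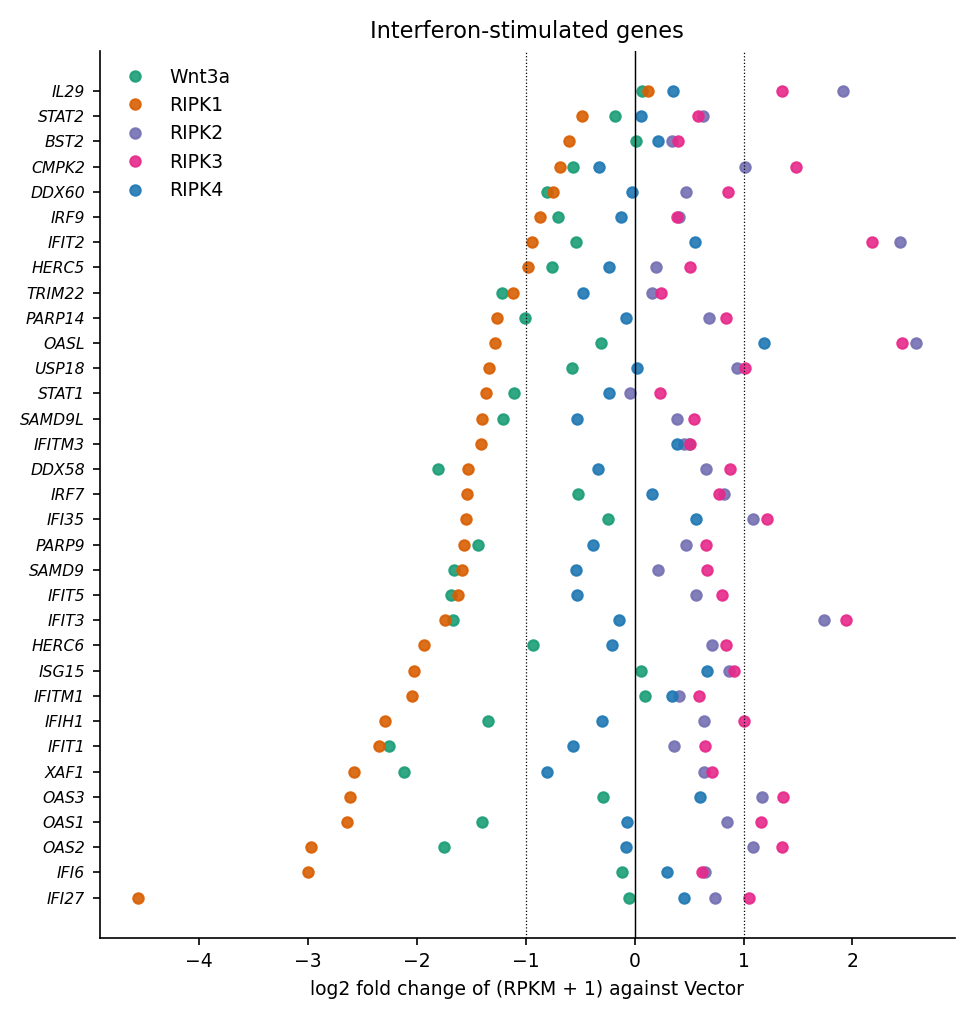
Log2 fold change against Vector, on log2(RPKM + 1), of the 33 kept interferon-stimulated genes (vertical axis, by symbol), with 1 point for each of the 5 other libraries and dotted lines at 2-fold lower and higher. The list median was -1.54 with RIPK1, -0.76 with Wnt3a, -0.08 with RIPK4, 0.65 with RIPK2 and 0.84 with RIPK3.

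RIPK2 was accompanied by higher medians of the interferon-stimulated, NF-kB target, and TGF-beta and BMP target lists. The interferon list was called higher at a median of 0.65, with 8 of 33 members at least 2-fold higher, led by OASL (7.42-fold, 6.08 to 9.14) and IFIT2 (6.34-fold, 5.60 to 7.21). The NF-kB list was called higher at 0.42 over 21 members, of which 15 stood above Vector and 6 below. The chemokine CCL5 (7.77 against 0.992 RPKM) was the 1 member at least 2-fold higher. TGF-beta and BMP targets were called higher at 0.58, with 6 of 23 members at least 2-fold higher, among them TGFBI (3.72-fold, 3.54 to 3.91), the BMP-responsive inhibitor ID3 (3.67-fold, 3.26 to 4.15) and TGFB1 (3.04-fold, 2.86 to 3.23). Immediate early genes (0.43), with FOSL2 at 9.03 against 2.32 RPKM, and stress response genes (0.40), with TRIB3 at 6.83 against 2.28, were called higher as well. Markers of endothelial (0.85) and of fibroblast and mesenchymal cells (0.45) were called higher too, and the latter share COL1A1 and FN1 with the TGF-beta list. Beyond the lists, IGFBP6 was 13.8-fold higher (8.70 to 23.3), the neuropeptide precursor VGF 6.55-fold (6.04 to 7.11), the collagen-crosslinking enzyme LOX 10.9-fold (8.39 to 14.4) and EMP1 5.21-fold (4.75 to 5.73). NACA2, PTTG3P, ANXA2P2 and EDARADD were also among the 10 largest rises and are uncertain for the reasons given with RIPK1.

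Lower transcripts with RIPK2 were led by CD24, a surface glycoprotein, at 2.33 against 14.0 RPKM (6.0-fold lower, 4.83 to 7.53), and SHISA3 at 6.76 against 31.6 RPKM. The extracellular matrix gene POSTN was 2.73-fold lower (2.58 to 2.88). POLR3G, MLN, TBCA, FGFBP3, SSB, FILIP1 and ATG4C completed the 10. Pluripotency genes were called lower at -0.41, with SOX2 2.35-fold lower (2.25 to 2.45), and neural progenitor genes at -0.37, with MAP2 2.48-fold lower, although TUBB3 of this list was 2.07-fold higher. Cholesterol and fatty acid synthesis genes were called lower at -0.41, with CYP51A1 at 7.27 against 16.3 RPKM and HMGCS1 at 26.2 against 50.9, and histone genes at -0.26. The Wnt list was not called, at 0.11.

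With RIPK2, 189 genes were at least 2-fold higher and 83 at least 2-fold lower, of which 147 and 65 were protein coding. The GC trend had a Spearman rho of 0.692, and with it removed the counts were 117 and 49, all 10 named rises and 8 of 10 named falls remained at least 2-fold apart, and SSB and ATG4C did not. The list calls above held after the removal. Farther from 0 than before were the interferon list (0.77, with 5 members at least 2-fold higher), histone (-0.54), neural progenitor (-0.50) and cholesterol synthesis genes (-0.46). Nearer 0 were TGF-beta and BMP targets (0.48), immediate early genes (0.19), NF-kB targets (0.26), stress response (0.33) and pluripotency genes (-0.24). Endothelial (0.77) and fibroblast markers (0.29) were nearer 0 too. Calls that ended were those of S phase and mitosis (-0.28, then -0.14) and of primitive streak genes (0.28, then -0.06). Cell death genes (0.22) were called higher and hypoxia genes (-0.15) lower only after it.

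RIPK3 gave values close to those of RIPK2. Interferon-stimulated genes were called higher at a median of 0.84, with 12 of 33 members at least 2-fold higher, among them OASL (6.77-fold, 5.54 to 8.35), IFIT2 (5.29-fold, 4.66 to 6.02) and OAS2 (2.62-fold, 2.5 to 2.75). NF-kB targets were called higher at 0.47 (0.28 with the GC trend removed), immediate early genes at 0.46, TGF-beta and BMP targets at 0.51 and stress response genes at 0.35. Endothelial (0.93) and fibroblast and mesenchymal markers (0.43) were called higher here too. IGFBP6 was 14.1-fold higher (8.89 to 23.8), VGF 8.34-fold (7.70 to 9.04), LOX 10.2-fold (7.86 to 13.5), EMP1 5.48-fold (5.0 to 6.02) and CCL5 8.56-fold (5.45 to 14.1). MYEOV and MARCH4 were at 7.74 and 6.81 RPKM against 0.985 and 0.834. GH1, the growth hormone gene, had the largest rise: it stood at 17.9 RPKM with 280 reads, at least 84.4-fold over the floor of 3 reads in the Vector library (two-sided limit 68.1), where it had none. It had 14 reads with RIPK1 and 0 in the other 4 libraries.

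The lower transcripts with RIPK3 again included CD24 (3.22 against 14.0 RPKM), SHISA3 (8.27 against 31.6) and POSTN (27.5 against 66.7), with FILIP1, FEZF1, FAM65B, EPHA3, POLR3G, TMEM64 and HMGN5. SOX2 was 2.17-fold lower (2.08 to 2.26). Lists called lower were histones (-0.50), cholesterol and fatty acid synthesis (-0.37), neural progenitors (-0.35), pluripotency (-0.27), and S phase and mitosis (-0.25), and all 5 held with the GC trend removed, the last 2 at -0.17 and -0.15. In total 175 genes were at least 2-fold higher and 69 at least 2-fold lower, of which 153 and 31 were protein coding. With the trend (Spearman rho 0.569) removed, the counts were 132 and 46, and POLR3G, POSTN and HMGN5 no longer stood 2-fold lower. Calls that ended then were Wnt targets (0.16, then 0.05), primitive streak (0.30, then 0.10), epidermal differentiation (0.37, then 0.15) and p53 targets (0.17, then 0.11), whereas cell death genes were called higher only then (0.24).

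The fold changes of RIPK2 and RIPK3 correlated across genes at 0.894, and at 0.864 with the GC trend removed, where unchanged libraries simulated against the same Vector library gave 0.507. With a reference of their own for each side the 6 choices averaged 0.457 (0.161 to 0.725), and 0.524 (0.445 to 0.640) with the GC trend removed as well. The highest, 0.724 and 0.725, had RIPK1 as the other reference, which may share a split with Vector. With Wnt3a or RIPK4 instead they lay between 0.161 and 0.458, and between 0.445 and 0.523 with the trend removed. Against Vector, RIPK2 and RIPK3 shared 123 genes at least 2-fold higher, where the simulated libraries gave 4 and independent lists 2.78. They shared 40 at least 2-fold lower (1 and 0.482). Removal of the GC trend left 86 and 22. With disjoint references 52 to 131 higher and 7 to 24 lower genes were shared, both counts highest where RIPK1 was the other reference. Among all pairs of libraries, RIPK2 and RIPK3 were closest with 42 genes at least 2-fold apart, followed by Wnt3a and RIPK4 with 52. RIPK1 and RIPK2 were farthest apart with 396 genes as deposited. With the GC trend removed they differed at 264, and Wnt3a and RIPK2 were farthest apart with 278.

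**Figure D4:**
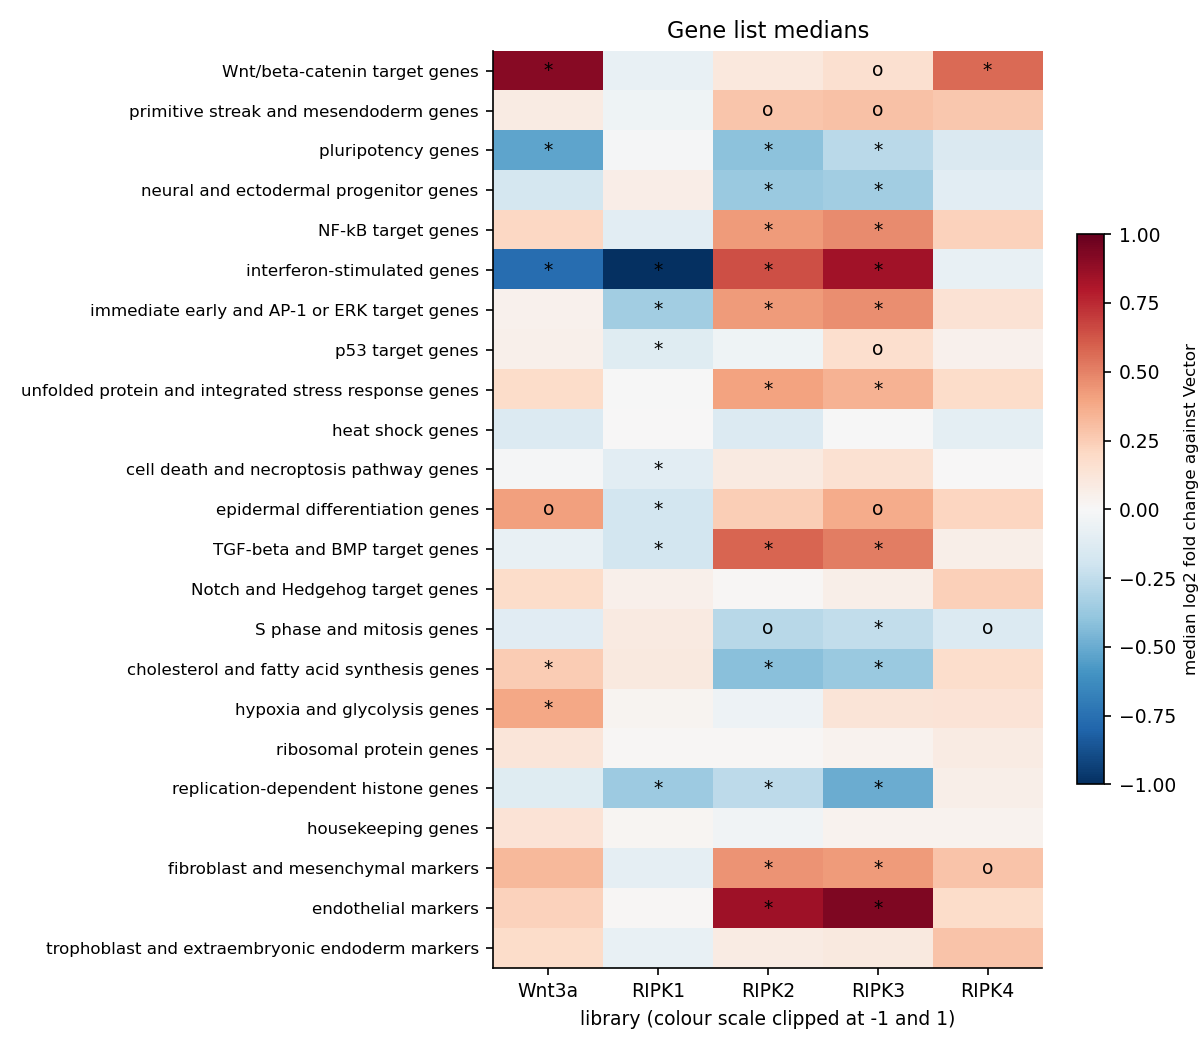
Median log2 fold change against Vector of the 23 gene lists with at least 3 kept members, as a colour scale limited to -1 and 1, with 1 column for each of the 5 other libraries. A star marks a list called the same way as deposited and with the GC trend removed and a circle a list called only as deposited; RIPK2 and RIPK3 share the interferon, TGF-beta and stress response calls, and Wnt3a and RIPK4 the Wnt target call.

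Similarity to Wnt3a was highest for RIPK4. Fold changes of RIPK4 and Wnt3a correlated across 11880 genes at 0.848 (Spearman 0.868), where unchanged libraries simulated against the same Vector library gave 0.536. The covariance was 0.132, and 0.0650 with the GC trend removed, against a simulated 0.00685. With a reference of their own for each side the 6 choices averaged 0.354 (0.0931 to 0.673), and 0.260 (0.183 to 0.401) with the GC trend removed as well. Of the genes at least 2-fold higher, 25 were shared, where the simulated libraries gave 4 and independent lists 0.317, and 24 of the lower ones (0 and 0.658). Removal of the trend left 17 and 16. Of the 46 genes at least 2-fold lower with RIPK4, 40 were small RNAs, so most of the shared lower genes were small RNAs as well. That class stood below Vector in every comparison. The simulation holds counting error alone, without differences between cultures, so an excess over it shows no shared effect, here or for the other pairs. Part of any excess may come from the shared Vector library.

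The other kinases gave lower correlations with Wnt3a. The kinase transcripts were not raised alike. RIPK1 went from 12.8 RPKM in Vector to 16.6 in its own library (1.30-fold), and RIPK2 from 11.8 to 27.4 (2.31-fold). RIPK3 went from 0 to 61.4 RPKM and RIPK4 from 0 to 17.9. By RPKM, RIPK2 in its library thus stood above RIPK4 in its own. Kinase protein was not measured here. The ranking therefore compares libraries and not kinases at equal levels. RIPK2 reached 0.624 (Spearman 0.685, simulated 0.515) with a covariance of 0.119 against 0.00641, RIPK3 0.574 (0.640, simulated 0.525) with 0.0961 against 0.00669, and RIPK1 0.379 (0.325, simulated 0.516) with 0.0436 against 0.00675. With the GC trend removed these became 0.360, 0.368 and 0.559, beside 0.743 for RIPK4, and the covariances 0.0392, 0.0392 and 0.0459. With disjoint references the means were 0.184 for RIPK2, -0.00891 for RIPK3 and -0.0722 for RIPK1, and each of these 3 ranged from below 0 to above 0. Genes at least 2-fold higher in both numbered 17 for RIPK2, 14 for RIPK3 and 11 for RIPK1, where the simulated libraries gave 4, 2 and 4 and independent lists 1.27, 1.18 and 0.236. Shared lower genes numbered 36, 34 and 28 (simulated 3, 1 and 2, independent 1.19, 0.987 and 0.930). After removal of the GC trend the higher ones were 11, 10 and 10 and the lower ones 15, 13 and 21, so that RIPK1 then shared the most lower genes with Wnt3a.

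Genes that set RIPK4 apart from the other kinases included Wnt targets. Since the kinase transcripts reached unlike levels, RIPK1 only 1.30-fold above Vector, a change missing in another library may not be a trait of its kinase. Against Vector, RIPK1, RIPK2 and RIPK3 alike, 9 genes were at least 2-fold higher with RIPK4: CDX1, CDX2, NKX1-2, MSX1, DACT1, RNF43, HES6, MIXL1 and NKD1. Of these, 6 are in the Wnt list, and all 9 were also at least 2-fold higher with Wnt3a than with Vector. HES6 was named only because it belongs to this set. The 3 genes lower against all 4 were small nucleolar RNAs, and none of them had 20 reads on average. MSX1 was higher than in Vector with RIPK2 and RIPK3 too (17.4 and 18.2 RPKM), below its 37.6 RPKM with RIPK4.

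Lists without a call in any comparison as deposited were heat shock, Notch and Hedgehog targets, ribosomal proteins, housekeeping genes, and trophoblast and extraembryonic endoderm markers. Their medians lay between -0.14 (heat shock, Wnt3a) and 0.28 (trophoblast, RIPK4). With the GC trend removed, heat shock (-0.11) and histone genes (-0.17) were called lower and housekeeping genes (0.19) higher with Wnt3a, as were neural progenitor (-0.35) and TGF-beta and BMP targets (-0.29), both lower. Of 21 haematopoietic markers only CD4 and CD68 were kept, too few for a call. CD68 stood at 4.89 and 4.80 RPKM with RIPK2 and RIPK3 against 1.94 in Vector, whereas CD4 stood lower, at 6.25 and 6.8 against 9.05.

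GC content moved with the libraries as follows. Genes were put in 5 equal groups by GC. In the group with the lowest GC (median 39.7%) the median log2 fold change was -0.41 with Wnt3a, -0.36 with RIPK2, -0.23 with RIPK3, -0.25 with RIPK4 and 0.01 with RIPK1. In the group with the highest GC (61.7%) it was 0.40, 0.35, 0.26, 0.36 and -0.04. The trend accounted for 47.8% of the variance of fold changes with Wnt3a, 41.2% with RIPK2, 26.0% with RIPK3, 45.1% with RIPK4 and 2.5% with RIPK1.

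**Figure D5:**
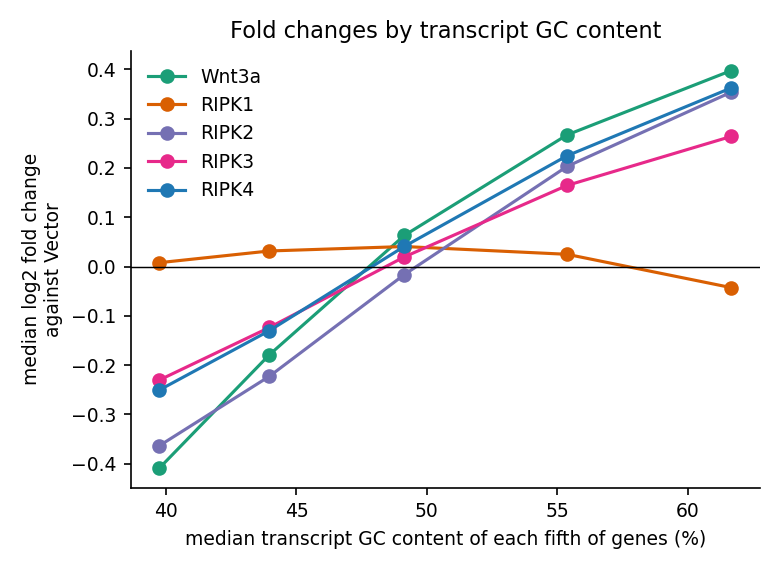
Median log2 fold change against Vector, on log2(RPKM + 1), for 5 equal groups of genes ordered by transcript GC content in percent, with 1 line per library. The lines of Wnt3a, RIPK2, RIPK3 and RIPK4 climb from between -0.41 and -0.23 to between 0.26 and 0.40, whereas RIPK1 stays between -0.04 and 0.04.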

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

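All tests in this section were chosen after the patterns they address were seen. Those of GC content, of the shared Vector library and of plasmid uptake were also set after their own values were known. The prediction for the library split was written before its own value. For 4 gene lists the libraries lay on opposite sides of Vector, with calls in both directions that held with the GC trend removed, and in each case the difference was not tested. Epidermal differentiation genes and p53 targets were also called in both directions, but their higher calls ended with the trend removed. Interferon-stimulated genes had medians of -0.76 with Wnt3a and -1.54 with RIPK1, and of 0.65 with RIPK2 and 0.84 with RIPK3. Immediate early and AP-1 or ERK targets had -0.35 with RIPK1, 0.43 with RIPK2 and 0.46 with RIPK3. TGF-beta and BMP targets had -0.19 with RIPK1, 0.58 with RIPK2 and 0.51 with RIPK3. Cholesterol and fatty acid synthesis genes had 0.26 with Wnt3a, -0.41 with RIPK2 and -0.37 with RIPK3.

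Fold changes of RIPK4 and Wnt3a against Vector moved together, with Wnt targets higher in both. With the trend removed and no library shared, a GC trend or the shared Vector library as the whole cause would put correlations around 0. This holds only if the other references carry no changes of their own. The 6 such correlations averaged 0.260, and the lowest was 0.183. RIPK2 and RIPK3, however, differed from Vector opposite to Wnt3a in interferon-stimulated genes, which can raise the correlation where they replace Vector beside RIPK4. RIPK1 may share a split with Vector. These correlations therefore cannot decide between such causes and a shared effect. A split of Vector and RIPK1 from the other 4 libraries as the whole cause would put Wnt targets at the level of random lists against the mean of RIPK2 and RIPK3, and their median was 0.49 (random lists -0.05 to 0.12). That RIPK4 may act on Wnt target genes in the manner of the ligand is a hypothesis found and tested on the same 6 libraries, and with no replicate a difference between single cultures stays open.

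Interferon-stimulated genes were low in the RIPK1 library. GC content as the whole cause is argued against, since the list median was -1.54 and random lists matched on GC had -0.07 to 0.09. With the small GC trend of this library (Spearman rho -0.0943), that outcome could be foreseen. Lower uptake of plasmid by the RIPK1 cells may account for part of it, since foreign DNA can raise these genes and RIPK1 itself was 1.30-fold above Vector. If the Wnt3a cells took no plasmid, this would put RIPK1 at their level or above it. Its median against Wnt3a was -0.40 (random lists -0.21 to 0.16), with 11 of 33 members at least 2-fold lower. Differences between these libraries followed GC content (Spearman rho -0.793), and that median was not recomputed with the trend removed. Ligand and time differed between them too, and the labels do not say whether the Wnt3a cells took plasmid. Lower uptake and an effect of RIPK1 therefore cannot be told apart here, and the effect of RIPK1 stays untested.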

How the results depend on the processing

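Removal of the GC trend, the minimum of 20 mean reads and the set without RIPK1 were chosen after seeing the data, as were all alternatives for the pairs of libraries, for the correlation of RIPK2 with RIPK3 and for the genes set apart in 1 library. The cause was not tested for any difference below unless given. With fewer or more genes passing a filter, counts change by construction. No named gene at least 2-fold apart changed direction. Of 2169 alternative values of named genes, 661 moved by more than the log2 distance from the middle to the end of their counting interval. That distance is a yardstick only, since all settings use the same reads. Of these, 335 moved with the median of the other libraries as reference and 230 with the GC trend removed. Another 52 moved with the pseudocount and 44 with rescaling. Calls of the Wnt list with Wnt3a and RIPK4 held under all 7 alternatives. For the other lists, 625 of 770 results kept direction and call, 41 gained a call and 35 lost it. Another 61 changed sign with no call in either setting, and 8, given below, changed sign where a call stood in at least 1 setting. Rescaling by median ratios and use of no minimum kept all 10 counts against Vector within 1.5 times. Depth limits genes of few reads: DKK1 and T stood at or near 0, and SP5 had at most 8 reads.

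With a pseudocount of 0.1, which gives low genes more weight, genes at least 2-fold higher and lower numbered 225 and 294 with Wnt3a, 69 and 112 with RIPK1, 346 and 145 with RIPK2, 299 and 116 with RIPK3, and 143 and 78 with RIPK4. The genes particular to RIPK4 numbered 17 higher and 10 lower. Genes set apart, above and below together, numbered 22 in Vector, 14 in Wnt3a, 34 in RIPK1, 24 in RIPK2 and 8 in RIPK4. In the main setting, those above and below were 4 and 5 in Vector, 1 and 3 in Wnt3a, and 0 and 18 in RIPK1. They were 8 and 0 in RIPK2, 1 and 4 in RIPK3, and 0 and 2 in RIPK4. Pairs differed at 89 genes for Wnt3a and RIPK4, 672 for RIPK1 and RIPK2, and 86 for RIPK2 and RIPK3.

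At a minimum mean RPKM of 5, genes at least 2-fold higher numbered 39 with Wnt3a, 12 with RIPK1, 102 with RIPK2, 103 with RIPK3 and 27 with RIPK4, and lower ones 39 with RIPK3 and 28 with RIPK4. Those particular to RIPK4 were 5 higher and 1 lower. Genes set apart were 3 in Vector, 2 in Wnt3a, 3 in RIPK2, 1 in RIPK3 and 0 in RIPK4. Pairs differed at 30 genes for Wnt3a and RIPK4, 261 for RIPK1 and RIPK2, and 11 for RIPK2 and RIPK3. With at least 20 mean reads, 21 genes were higher with RIPK1, 41 lower with RIPK3, 19 lower with RIPK4, and 0 lower in the set particular to RIPK4. Without RIPK1 as a reference, that set held 6 lower genes.

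Against the median of the other transfected libraries, genes at least 2-fold higher and lower numbered 32 and 44 with Wnt3a, 15 and 140 with RIPK1, 112 and 28 with RIPK2, 89 and 28 with RIPK3, and 23 and 28 with RIPK4. This reference turned the direction of the immediate early list with Wnt3a (-0.13), of cell death genes (-0.0907) and TGF-beta and BMP targets (-0.20) with RIPK4, and of endothelial markers with RIPK1 (-0.58) and RIPK4 (-0.24). With the GC trend removed, counts were 41 and 84 with Wnt3a and 117 and 49 with RIPK2. Its removal turned primitive streak genes with RIPK2 (-0.0630) and, with RIPK4, TGF-beta and BMP targets (-0.12) and histone genes (-0.10).

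The Wnt list with RIPK1, not called in the report, was called lower at -0.14 with a pseudocount of 0.1, -0.0423 with no minimum, -0.16 at a minimum of 5, -0.22 against the other libraries and -0.11 with 20 mean reads. With RIPK3 its call was lost at 0.18 with that pseudocount, 0.0708 with no minimum and 0.12 at a minimum of 5, at 0.13 after rescaling, at 0.0483 with the GC trend removed and at 0.14 with 20 mean reads. With RIPK2 its median moved to -0.0809 with the GC trend removed.

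Correlations with Wnt3a for RIPK1, RIPK2, RIPK3 and RIPK4 were 0.403, 0.602, 0.554 and 0.829 with a pseudocount of 0.1, and 0.354, 0.666, 0.604 and 0.858 at a minimum of 5. With no minimum they moved to 0.605 for RIPK2 and 0.831 for RIPK4, and with 20 mean reads to 0.351 for RIPK1 and 0.864 for RIPK4. With the GC trend removed they were 0.559, 0.360, 0.368 and 0.743, with disjoint references -0.0722, 0.184, -0.00891 and 0.354, and with both 0.123, -0.0908, -0.105 and 0.260. RIPK4 had the highest correlation under each of these settings.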

Other observations

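All tests in this section were chosen after the patterns they address were seen. Those of carry-over and of transcript classes were also set after their own values were known. The predictions for paralogs and for a plasmid sequence were written before their own values, although GH1 at 0 reads in the libraries without these plasmids was part of the pattern. Markers of endothelial cells were higher with RIPK2 and RIPK3. Of 13 markers 8 were kept, with list medians of 0.85 and 0.93, above all 10000 random lists, and of 0.77 and 0.83 with the GC trend removed. The vascular receptor TIE1 stood at 44.4 and 41.5 RPKM against 19.7 in Vector, the TGF-beta co-receptor ENG at 11.8 and 11.2 against 4.14, the junction protein ESAM at 6.78 and 6.31 against 2.03, and the endothelial cadherin CDH5 at 10.9 and 11.5 against 5.40. With Wnt3a, RIPK1 and RIPK4 the list was not called, at 0.23, 0.01 and 0.19. Fibroblast and mesenchymal markers were called higher at 0.45 with RIPK2 and 0.43 with RIPK3 over 12 of 20 members, and at 0.29 and 0.26 with the GC trend removed. The collagen genes COL1A1 (82.6 and 83.0 RPKM against 32.6) and COL5A1 (58.5 and 59.8 against 28.8) were higher, whereas POSTN was lower, as given above. COL1A1 and FN1 stand in the list of TGF-beta and BMP targets as well. The list was not called with Wnt3a (0.32) or RIPK1 (-0.09).

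The libraries of RIPK2 and RIPK3 differed from each other mainly in short and copied genes. Of 42 genes at least 2-fold apart, 38 were higher with RIPK2, among them 22 small RNAs, 11 pseudogenes and 4 protein-coding genes (BSX, PABPC3, EDARADD and CSNK2A1P, of which the last is a retrocopy and PABPC3 lacks introns). Of the 4 higher with RIPK3, GH1 was the 1 that codes for protein. PABPC3 and CSNK2A1P were named after their values were seen. Over all 137 kept pseudogenes the median against Vector was 0.14 with RIPK2, above 99.5% of matched random lists, and 23 were at least 2-fold higher and none 2-fold lower, beside 9 higher with RIPK1 and 7 with RIPK3. Over the 101 pseudogenes with a GC value, 10 were higher with RIPK2 both as deposited and with the GC trend removed. The medians of all 137 were 0.08 with Wnt3a, -0.01 with RIPK1, -0.00085 with RIPK3 and 0.04 with RIPK4, none outside the central 95% of random lists. The 173 small RNAs, with 9.67 reads per library in the median, stood below Vector in all 5 libraries, at -0.28 with Wnt3a, -0.21 with RIPK1, -0.08 with RIPK2, -0.32 with RIPK3 and -0.30 with RIPK4, each below the central 95% of matched random lists. These are not separate observations, since all 5 share the Vector library. The random lists were matched on RPKM and not on reads, so their spread may be too narrow for this class.

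Reads of GH1 appeared in the RIPK3 library (280) and the RIPK1 library (14) and in none of the others. Carry-over from the RIPK3 into the RIPK1 library is argued against, since it would have brought 158 reads of RIPK3 itself (lower 95% bound 134), and 0 were counted. Reads shared among the paralogs of the locus are argued against by GH2, CSH1, CSH2 and CSHL1 together holding 0.714% of the number of GH1 reads in that library. Growth hormone sequence carried by the RIPK3 and RIPK1 plasmids and a rise of the cells' own GH1 cannot be told apart here: the pituitary genes POU1F1, PRL, GHRHR, CGA and TSHB had 0 reads with RIPK3, but were at or near 0 in all libraries, and the plasmid sequences were not analysed here.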
